A study of Homo sapiens and Mus musculus with 19 samples.

How the data were processed

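RNA from 19 libraries in 7 groups was measured by sequencing. The 4T1 line, a mouse mammary carcinoma line, had been injected under the skin of BALB/c mice with an intact immune system (100000 cells per injection, per the labels' protocols). Its tumours were wild type (WT), KDM1B knockout (KO) or KDM1A KO, with 3 libraries of each genotype. MDA-MB-231, a human triple-negative breast cancer line, was sequenced as WT and KDM1B KO tumours grown under the skin of athymic nude mice after injection of 3000000 cells, with 3 libraries per genotype. It was also sequenced as WT and KDM1B KO cells in culture, with 2 libraries per genotype. KDM1B and KDM1A are the flavin-dependent histone demethylases that remove methyl groups from histone tails. Total RNA was taken up in Trizol, treated with DNase on a column and made into standard Illumina libraries, per the labels' protocols. The strandedness and the edited exons were not given in the sources used here. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may in part be technical.

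The authors deposited 3 tables, for the 4T1 tumours, the MDA-MB-231 tumours and the MDA-MB-231 cultures. Each table held whole-number read counts per gene and library, which the authors left unnormalized, per the file headers and the values. Each table also held RPKM per gene and library, normalized by the authors for gene length and depth, per the file headers. Reads were trimmed with Trim Galore 0.4.5, aligned with STAR 2.5.4 and counted with featureCounts, and edgeR 3.24.3 was used, per the submitters' processing notes. Those notes name the builds hg38 and mm9 without saying which table used which. The tables had 1 line per RefSeq accession, with the same values on every line of a gene, so each gene was taken once. That left 23426 genes in the 4T1 table and 27011 in each MDA-MB-231 table. In the MDA-MB-231 tumour table only human genes were counted, and how reads of the mouse host were set apart was not given in the sources used here.

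Total counts ran from 22923212 to 47003147 in the 4T1 tumours, from 37551440 to 49972382 in the MDA-MB-231 tumours and from 77192063 to 91333016 in the cultures. No pair of libraries of a group agreed within sampling noise. The chi-square per degree of freedom between replicates ran from 8.82 for the WT cultures to 167 for WT replicates 1 and 2 of the MDA-MB-231 tumours. All libraries were therefore kept as separate replicates.

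The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, the filterByExpr filter by group and no robust fitting. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. After the filter, 15462 genes were tested in the 4T1 tumours, 14452 in the MDA-MB-231 tumours and 15039 in the cultures, which held at least 99.95% of the counts of each library. The 9 4T1 tumours entered 1 fit with 6 residual degrees of freedom, the 6 MDA-MB-231 tumours a fit with 4 and the 4 cultures a fit with 2. The common biological coefficient of variation was 0.319 in the 4T1 tumours, 0.196 in the MDA-MB-231 tumours and 0.21 in the cultures. A further fit over the 10 MDA-MB-231 libraries and 15603 genes tested whether the KO effect differed between tumour and culture. Levels are TMM-scaled CPM, in proportion to each gene's share of its library, given as mean ± SD over libraries. Fold changes are log2 values ± SE.

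Before the data were examined, 17 pathway lists, 13 lists of cell type markers, the tests, their designs and most alternatives had been fixed. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Benjamini-Hochberg adjustment ran over the lists of a comparison, and a list needed at least 3 tested members. Fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. Genes are named in the text by a rule fixed at the same time. It took the demethylases themselves, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean log2 CPM of at least 2 whose KO and WT libraries did not overlap, and up to 4 called members of each list with the smallest adjusted p. Where nothing was called, it took the 3 rising and 3 falling genes of smallest p. Genes outside the rule are marked as chosen after their values were seen. Symbols of both species were joined in upper case for comparisons between the lines.

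The edgeR tests against WT and of the tumour-culture difference were tried on simulated data drawn from the real means and library sizes. In each, 200 genes were changed, 100 of them 2-fold and 100 of them 4-fold. The changed genes were drawn only from those with a mean of at least 4 CPM, in tumour and culture alike for their difference. The shares recovered therefore do not cover genes of lower levels. In the simulation of KDM1B KO against WT 4T1 tumours, 48% of the genes changed 2-fold and 91% of those changed 4-fold were recovered among 15204 genes. For KDM1A KO against WT these shares were 48% and 90% among 15220 genes. They were 83% and 99% among 14253 genes for the MDA-MB-231 tumours, 67% and 91% among 14803 genes for the cultures, and 36% and 95% among 15330 genes for the difference between tumour and culture effects. Unchanged genes called numbered 8, 12, 16, 20 and 10 in the same order. With 30 simulated lists camera found the 1 raised 2-fold and called 0 others in each comparison against WT. Each gene was drawn independently, so the simulation does not show how often camera at the preset correlation calls an unchanged list of correlated genes. The comparison of the knockouts with each other and the other tools were not simulated.

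The replicate numbers came from the labels, which do not say what a number marks. In the 4T1 table the deviations of KDM1A KO and WT tumours from their group means correlated at 0.291, 0.317 and 0.277 for the numbers 1, 2 and 3, so these numbers were treated as pairing the samples of that comparison. The other comparisons had at least 1 same-numbered pair at or under 0.1 or only 2 pairs.

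The alternatives tried were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no filter and a stricter filter on low counts, a 2-fold threshold, the replicate number as a block, fits of only the 6 tumours compared, limma-trend on log2(RPKM + 1), and each library left out in turn. A robust fit, list counts with each library left out and a recount of 2-fold calls after regional medians were taken off were added after the data had been seen. Gene positions and lengths for human genes came from RefSeq on GRCh38.p14, and their GC content from GENCODE transcripts. No mouse coordinates were used here. Tables and figures were made in Python 3.11.15.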

Results

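RNA sequencing compared tumours and cells with and without KDM1B, in a mouse and a human breast cancer line, with KDM1A KO tumours beside them in the mouse line. The 4T1 series held 3 WT, 3 KDM1B KO and 3 KDM1A KO tumours, with total counts of 22923212 to 40057520, 29766000 to 40957059 and 40670266 to 47003147. The MDA-MB-231 series held 3 WT and 3 KDM1B KO tumours, at 37551440 to 46516325 and 38884886 to 49972382 counts. It also held 2 WT and 2 KDM1B KO cultures, at 77192063 to 84820494 and 81376679 to 91333016 counts. The stated aim was the effect of KDM1B loss on cancer cells in culture and on the tumours they form.

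The targeted genes were read in every library first. In the 4T1 tumours Kdm1b stood at 11.8, 8.82 and 12.6 CPM in the KDM1B KO libraries and at 21.8, 17.2 and 14.7 CPM in the WT libraries, so every KO library lay below every WT library. The log2 fold change was -0.69 ± 0.20, which did not pass (edgeR adjusted p = 0.159), and in the KDM1A KO tumours Kdm1b was at 17.1, 16.0 and 17.7 CPM. Kdm1a fell from 127 ± 6.95 CPM in WT to 40.4 ± 5.10 CPM in the KDM1A KO tumours (SD, n = 3 each), a log2 fold change of -1.66 ± 0.13 (edgeR adjusted p = 0.0014), with 44.6, 41.8 and 34.7 CPM in the single libraries. In the KDM1B KO tumours Kdm1a was at 112 ± 7.12 CPM (log2 fold change -0.19 ± 0.13, edgeR adjusted p = 0.544). Human KDM1B (gene ID 221656, chromosome 6, 18155422 to 18223854 on GRCh38) was at 20.1, 18.3 and 17.7 CPM in the KO tumours and at 29.8, 58.8 and 33.2 CPM in the WT tumours, and it fell by 1.12 ± 0.24 on the log2 scale (edgeR adjusted p = 0.0263). In culture KDM1B was at 27.6 and 16.2 CPM in the KO libraries against 47.8 and 48.4 CPM in WT (log2 fold change -1.14 ± 0.27, edgeR adjusted p = 0.601). The 61 genes read from 0 to 20 Mb on chromosome 6, around KDM1B, had a median log2 difference from WT of -0.433 in KO culture replicate 1. This median was -0.0473 in KO culture replicate 2 and 0.07 in the KO tumours. Part of the lower KDM1B value in replicate 1 may therefore belong to its region, which was not tested. KDM1A (gene ID 23028, chromosome 1, 23019468 to 23083689 on GRCh38) was at 117 ± 5.40 CPM in KO and 117 ± 9.50 CPM in WT tumours. The labels do not give the edited exon, so a KO transcript that is still counted says nothing of the protein.

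**Figure D1:**
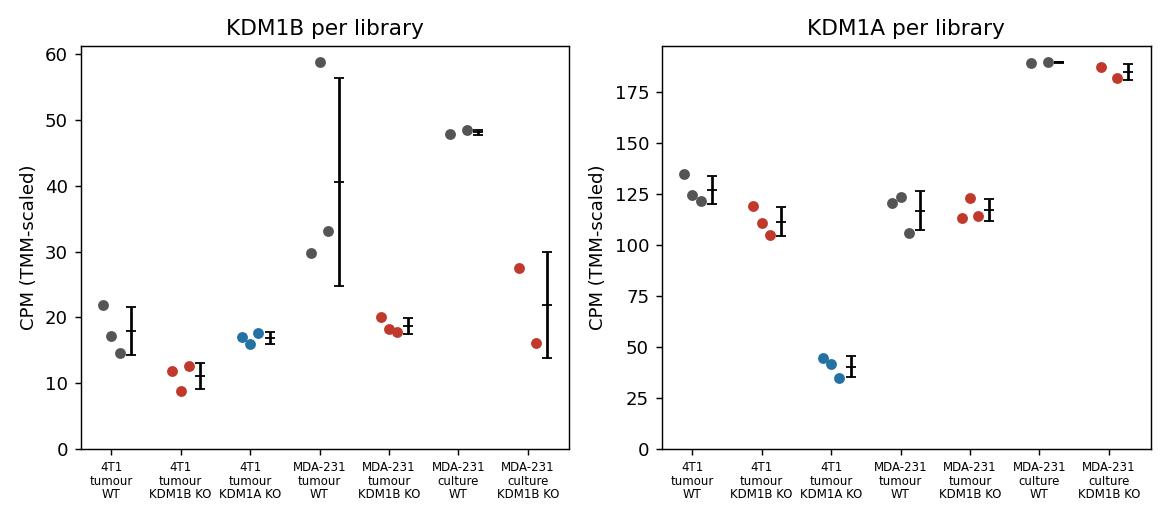
TMM-scaled CPM of KDM1B (left) and KDM1A (right) on linear axes from 0, 1 point per library, with the group mean ± SD beside the points. Kdm1a in the 4T1 KDM1A KO tumours averages 40.4 CPM against 127 CPM in WT, and KDM1B in each KDM1B KO group lies below its WT group.

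The comparison of KDM1B KO with WT 4T1 tumours asked what changes in tumours of KDM1B-deficient cells in immune-competent mice. Of 39 tested interferon-stimulated genes 15 rose and none fell. Ifit3, an interferon-induced antiviral protein, was at 49.0 ± 10.1 CPM in KO and 8.58 ± 1.34 CPM in WT tumours (SD, n = 3 each), a log2 fold change of 2.51 ± 0.27 (SE, edgeR adjusted p = 0.00574). Of 13 cytotoxic and NK cell genes 4 rose, among them Gzma, which encodes a granzyme, at 6.83 ± 2.47 against 0.958 ± 0.442 CPM (2.85 ± 0.45, adjusted p = 0.0244). The claudin Cldn7, of epithelial junctions, rose from 3.55 ± 1.09 to 22.3 ± 2.81 CPM (2.66 ± 0.28, adjusted p = 0.00574). Bmp7, a secreted bone morphogenetic protein, fell from 94.9 ± 13.3 to 2.04 ± 2.54 CPM (-5.48 ± 0.83, adjusted p = 0.0206).

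Over all 15462 genes tested in the 4T1 tumours, 121 were called between KDM1B KO and WT, 72 higher and 49 lower in KO. Large rises among separated genes were in Dsc2, a desmosomal cadherin (3.40 ± 0.48), and Dio2, the deiodinase that activates thyroid hormone (3.20 ± 0.56). Further rises were in Xlr (2.73), Ifit3b (2.72), Akr1c13, an aldo-keto reductase (2.52), Txk, a kinase of T cells (2.46), and Fancc, a Fanconi anaemia repair gene (2.43). Ifit3 and Ifit3b are close paralogs, so reads could have been split between them. After Bmp7, the largest falls were in Celsr1, a planar polarity cadherin (-4.11 ± 0.44), Ppp1r14c, a phosphatase inhibitor (-3.20), Ntn1, a secreted guidance cue (-2.96), and Gipc2 (-2.65). Mgp, an inhibitor of calcification (-2.63), Hhip, a decoy receptor for hedgehog ligands (-2.29 ± 0.18, adjusted p = 0.00194), Cib2 (-2.16), Gpm6b, a membrane proteolipid (-1.87), and Ace, the angiotensin-converting enzyme (-1.81 ± 0.18), followed. Chance separates 10% of genes completely with 3 libraries against 3, and 18.3% of the tested genes were separated here.

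All 39 interferon-stimulated genes had positive fold changes in the KDM1B KO 4T1 tumours, with a median of 1.00, and 30 rose when adjusted over the list alone. Camera gave an adjusted p of 2.3e-42, and adjusted p = 0.0169 with an estimated correlation. Besides Ifit3, Oas2 and Oas3, oligoadenylate synthetases that sense viral RNA (2.08 and 1.99), and Ifi44 (1.44) led the list. The double-stranded RNA sensor Ifih1 (0.90) was the 1 of 16 sensing and silencing genes that rose, a list that did not pass camera (adjusted p = 0.143). Of 39 cytokine receptor and JAK-STAT genes, Socs1, the feedback inhibitor of interferon signalling (1.66), and Stat2, which carries the interferon signal to the nucleus (0.87), rose. The list had 5 rises when adjusted over the list alone and did not pass (adjusted p = 0.181). Of 44 cytokines Ccl5, a T cell attractant, rose (1.90), and 7 rose and 4 fell when adjusted over the list alone (adjusted p = 0.568). Havcr2, an inhibitory receptor of lymphocytes, was the 1 of 19 checkpoint genes that rose (1.24; 4 up and 1 down adjusted over the list alone). The list's call at adjusted p = 0.0108 was lost at adjusted p = 0.403 with an estimated correlation and without WT replicate 3 (adjusted p = 0.218). The 8 class II antigen presentation genes had a median of 0.97 (adjusted p = 4.68e-05, and adjusted p = 0.402 with an estimated correlation). The 17 class I genes did not pass (median 0.11, adjusted p = 0.324).

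Among the cell type markers of the same comparison, 4 of 13 cytotoxic and NK cell genes rose over all genes, and 10 rose and 1 fell when adjusted over the list alone. Their median was 1.96 (adjusted p = 5.45e-14, and adjusted p = 0.00855 with an estimated correlation). Beside Gzma these were Prf1, the pore-forming perforin (1.96), Nkg7, a granule protein (2.05), and Klrk1, an activating receptor of NK cells (2.02). Of 16 T cell genes, Cd4, the coreceptor of helper T cells, rose (1.57), and 13 rose when adjusted over the list alone. The median was 1.55 (adjusted p = 7.67e-12, and adjusted p = 0.157 with an estimated correlation). Cd4 was no longer called with any 1 of the 9 libraries left out. Irf8, a regulator of dendritic cells, was the 1 of 10 dendritic cell genes that rose (0.98; 3 adjusted over the list alone; adjusted p = 0.00942, adjusted p = 0.272 with an estimated correlation and 0.0533 without KO replicate 3). The 14 macrophage genes had a median of 0.67 (5 up adjusted over the list alone; adjusted p = 1.67e-05, and adjusted p = 0.402 with an estimated correlation). The 14 neutrophil genes had a median of -1.04 (4 down adjusted over the list alone; adjusted p = 1.08e-04, and adjusted p = 0.402 with an estimated correlation). Skeletal muscle markers had a median of 4.11, with 11 of 12 up when adjusted over the list alone (adjusted p = 3.06e-11, and adjusted p = 0.272 with an estimated correlation). Acta1, muscle actin, chosen after its values were seen, was at 85.9 ± 109 CPM in KO and 0.213 ± 0.109 CPM in WT tumours and did not pass (adjusted p = 0.116). Erythroid genes had a median of -1.14 (adjusted p = 0.0415, adjusted p = 0.545 with an estimated correlation, and 0.0988, 0.136 and 0.277 without KO replicates 2 and 3 and WT replicate 2). The markers of B cells, fibroblasts, endothelium, adipocytes, keratinocytes and mammary epithelium did not pass camera.

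Of the remaining pathways in KDM1B KO 4T1 tumours, 3 of 28 epithelial-mesenchymal transition genes rose, namely the claudins Cldn3 (2.37 ± 0.22, adjusted p = 0.00328) and Cldn7, and Tgfbi, a matrix adhesion protein (0.94). The list's median was -0.115 and its mean 0.0957, and it did not pass (adjusted p = 0.396). Ier3, an early response gene, was the 1 of 27 NF-kB genes that fell (-1.29), and Igf2r, the imprinted receptor that clears insulin-like growth factor, was the 1 of 19 imprinted genes that fell (-1.03). The cell cycle genes had a median of 0.30 (adjusted p = 0.00464, adjusted p = 0.621 with an estimated correlation, and 0.116 and 0.197 without KO and WT replicate 3). The hypoxia and glycolysis genes had a median of -0.20 (adjusted p = 0.00464, and adjusted p = 0.621 with an estimated correlation), a call that ended without KO replicate 1 (adjusted p = 0.457, median 0.0487). The 14 demethylase partner genes had a median of -0.165 (adjusted p = 0.0245, adjusted p = 0.272 with an estimated correlation, and 0.12 and 0.0666 without KO replicate 3 and WT replicate 1). The proteases and the cholesterol, stress response and immediate early genes did not pass.

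The count of called genes in KDM1B KO 4T1 tumours rested on single libraries. It was 15 without WT replicate 1, 38 and 50 without KO replicates 1 and 2 and 77 without KDM1A KO replicate 1, and 831 with DESeq2. The interferon-stimulated genes called up numbered 1 without WT replicate 1, 7 without KO replicate 1 (median 0.99), in which muscle markers were highest, and 8 without KO replicate 2. The cytotoxic genes called numbered 0 in edgeR without WT replicate 1 or KO replicate 1 or 2, 1 without KO replicate 3, and 2 without WT replicate 3 or KDM1A KO replicate 1. With all libraries 11 cytotoxic genes were at an unadjusted p under 0.05, and DESeq2 called 7 and limma 5.

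**Figure D2:**
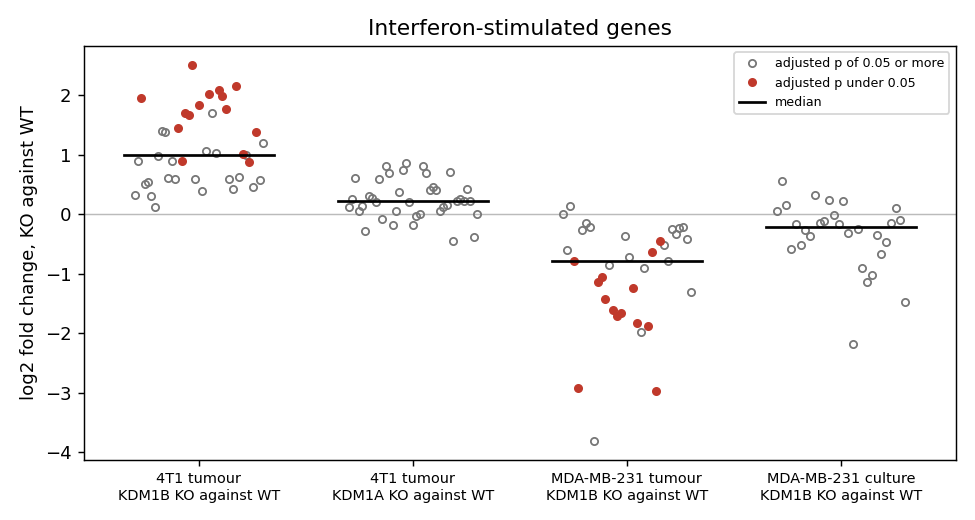
Log2 fold change of each tested interferon-stimulated gene, KO against WT, 1 point per gene in alphabetical order, with filled points at an edgeR adjusted p under 0.05 and bars at the median. The medians are 1.00 in 4T1 KDM1B KO tumours, 0.23 in 4T1 KDM1A KO tumours, -0.78 in MDA-MB-231 KDM1B KO tumours and -0.21 in the KDM1B KO cultures.

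The comparison of KDM1A KO with WT 4T1 tumours asked what loss of the related demethylase changes in the same model. H19, an imprinted non-coding RNA, rose from 74.0 ± 28.4 to 1437 ± 799 CPM (SD, n = 3 each), a log2 fold change of 4.28 ± 0.62 (edgeR adjusted p = 0.0161). Cldn9, a claudin of tight junctions, rose from 2.05 ± 0.339 to 53.7 ± 8.91 CPM (4.71 ± 0.47, adjusted p = 0.00518). Of 14 neutrophil markers 4 fell, and the list's call at adjusted p = 2.4e-05 was lost at adjusted p = 0.459 with an estimated correlation. S100a8, a calcium-binding protein abundant in neutrophils, went from 147 ± 7.79 to 19.3 ± 10.7 CPM (-2.92 ± 0.64, adjusted p = 0.0453, and 0.0529 with the replicate number as a block), and Cxcl2, a neutrophil attractant, from 38.7 to 2.15 CPM (-4.17 ± 0.71, adjusted p = 0.0248).

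In this comparison 432 genes were called, 252 higher and 180 lower in KDM1A KO, and 27.2% of the tested genes were separated against the 10% of chance. Further rises were in Arfgef3 (4.47), Kcnh3, a potassium channel (4.20), Crb3, an apical polarity gene (3.73), Otop1, a proton channel (3.65), Tjp3, a tight junction scaffold (3.57 ± 0.27, adjusted p = 0.0014), Rnf128, a ubiquitin ligase (3.42), and Cilp2, a cartilage matrix gene (3.28). Ptgds, a prostaglandin D synthase, was at 14.6 ± 9.29 CPM in KO and 0.0305 ± 0.0529 CPM in WT tumours (adjusted p = 0.0167). Further falls were in the stefins Stfa2 (-4.45) and Stfa2l1 (-3.65), near-identical cysteine protease inhibitors whose reads are uncertain, Bmp7 (-3.75 ± 0.76; adjusted p = 0.0375, and 0.051 with the replicate block), Dynap (-3.06), Tmprss6, a membrane protease (-2.64), S100a9, the partner of S100a8 (-2.54), Ccl3, a chemokine (-2.05), and Hcar2, a receptor for hydroxybutyrate (-2.04).

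Of 44 cytokines 5 fell in the KDM1A KO tumours and 9 when adjusted over the list alone. They were Cxcl3 (-4.76), Cxcl2, Ccl3, the epithelial cytokine Tslp (-0.93) and Il23a, chosen after its value was seen (-1.25). The list's median was -0.215 (adjusted p = 0.00449, adjusted p = 0.459 with an estimated correlation and 0.0603 without WT replicate 2). Of 27 NF-kB genes 3 fell, Ier3 (-1.29), Tnfaip2 (-0.86) and Nfkbia, the inhibitor induced by NF-kB itself (-0.78, adjusted p = 0.0557 with the replicate block; 3 adjusted over the list alone; median -0.32, adjusted p = 0.00155, and adjusted p = 0.459 with an estimated correlation). Jun, an AP-1 transcription factor, was the 1 of 20 immediate early and heat shock genes that fell (-0.82; 5 adjusted over the list alone; median -0.34, adjusted p = 2.4e-05, and adjusted p = 0.459 with an estimated correlation). The hypoxia and glycolysis genes had a median of -0.51 (1 up and 8 down adjusted over the list alone; adjusted p = 3.38e-05, and adjusted p = 0.525 with an estimated correlation). Of 39 receptor and JAK-STAT genes Socs1 rose (1.29) and Il1rn, the interleukin-1 receptor antagonist, fell (-1.16), and the list's mean of 0.0177 and median of -0.00145 differed in sign (adjusted p = 0.819). Cldn3 rose (1.48) and Tjp1, a tight junction scaffold, fell (-1.10) among 28 epithelial-mesenchymal transition genes (adjusted p = 0.298). Phgdh, of serine synthesis, rose (1.15) and Ppp1r15a (-1.24) and Atf3 (-1.12), of the stress response, fell among 20 genes (median 0.0829, mean -0.0328, adjusted p = 0.831). Mmp1a, a collagenase, was the 1 of 25 protease genes that fell (-3.17; median 0.0585, mean -0.0464, adjusted p = 0.966). Hmg20b, a KDM1A partner, rose (0.69, adjusted p = 0.0467, and 0.0611 with the replicate block) beside the fall of Kdm1a (adjusted p = 0.0189 for the 14 partner genes, adjusted p = 0.459 with an estimated correlation and 0.056 without KDM1A KO replicate 2). The 39 interferon-stimulated genes had a median of 0.23 and did not pass (adjusted p = 0.119), with 0 called by edgeR, 5 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma.

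Of 14 neutrophil markers 4 fell in KDM1A KO tumours, S100a8, S100a9, the surface marker Ly6g (-3.13) and the chemokine receptor Cxcr2 (-1.85), and 7 fell when adjusted over the list alone. With the replicate number as a block 2 were called, and S100a8, S100a9 and Ly6g were at adjusted p = 0.0529, 0.0599 and 0.0608. The median of the neutrophil list was -1.51 (adjusted p = 2.4e-05, and adjusted p = 0.459 with an estimated correlation). Of 14 macrophage markers 3 rose, Aif1 (1.04) and the complement genes C1qa (1.16) and C1qc (0.91), and 7 rose when adjusted over the list alone, while with the replicate block 1 was called and Aif1 and C1qa were at adjusted p = 0.051 and 0.0578 (median 0.91, adjusted p = 3.38e-05, and adjusted p = 0.459 with an estimated correlation). Class II antigen presentation had a median of 0.97 (adjusted p = 0.00709, adjusted p = 0.68 with an estimated correlation, and 0.103 and 0.274 without KDM1A KO replicate 1 and WT replicate 3). Dendritic cell genes had a median of 0.84 (adjusted p = 0.0211, adjusted p = 0.459 with an estimated correlation, and 0.0605 and 0.113 without KDM1A KO replicate 2 and WT replicate 3). Fibroblast markers (0.54; adjusted p = 0.0189, adjusted p = 0.835 with an estimated correlation, and 0.0602, 0.259 and 0.285 without KDM1A KO replicates 1 and 2 and WT replicate 3) and muscle markers (1.78; adjusted p = 0.0189, adjusted p = 0.862 with an estimated correlation and 0.626 without KDM1A KO replicate 3) passed camera. Erythroid markers (-1.53; adjusted p = 0.0265, adjusted p = 0.541 with an estimated correlation, and 0.179, 0.0934 and 0.0718 without KDM1A KO replicate 1 and WT replicates 2 and 3) also passed camera, and the other 18 lists did not. Among these, the checkpoint genes had a median of 0.0843 and a mean of -0.0251. The sensing genes had a median of 0.128 with a camera direction of lower, as had the keratinocyte genes with 0.0587.

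The number of genes called between KDM1A KO and WT was 4 without WT replicate 1 and 1516 without WT replicate 3. It was 75 without WT replicate 2, 41, 87 and 57 without KDM1A KO replicates 1, 2 and 3, and 1688 with DESeq2. Rn18s, the 18S ribosomal RNA, held 0.409% to 0.571% of counts in KDM1A KO tumours, 0.524% in WT replicate 3 and 0.424% in KDM1B KO replicate 3. In WT and KDM1B KO replicates 1 and 2 it held 0.199% to 0.283%, at lower total counts. KDM1A KO was largely confounded with this split of the libraries, and wholly so against WT without WT replicate 3. Neutrophil genes called by edgeR numbered 0 without any 1 of KDM1A KO replicates 1, 2 and 3, WT replicates 1 and 2 or KDM1B KO replicate 2, and 7 without KDM1B KO replicate 3. With all libraries 9 were at an unadjusted p under 0.05, and DESeq2 called 7 and limma 4. Macrophage and stress response genes called by edgeR numbered 0 without any 1 of KDM1A KO replicates 1, 2 and 3 and WT replicates 1 and 2. With all libraries 8 and 7 were at an unadjusted p under 0.05, and DESeq2 called 7 and 5 and limma 3 and 2. Without KDM1B KO replicate 2 the stress response genes numbered 1. Cytokines numbered 0 without KDM1A KO replicate 1 or WT replicate 1 or 2, and 2 without KDM1A KO replicate 2 or 3. With all libraries 14 cytokines were at an unadjusted p under 0.05, and DESeq2 called 10 and limma 4.

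Set directly against each other, the 2 knockouts in 4T1 tumours differed in interferon-stimulated genes and in H19. Of 39 interferon-stimulated genes 13 were higher in KDM1B KO than in KDM1A KO tumours and none lower, 22 when adjusted over the list alone, with a median of 0.80 (adjusted p = 1.84e-24, and adjusted p = 0.0517 with an estimated correlation). Ifi44 was at 224 CPM in KDM1B KO and 72.2 CPM in KDM1A KO tumours (1.63 ± 0.19, adjusted p = 0.00372), and Ifit3 differed by 1.65 ± 0.26. Of 13 cytotoxic genes 3 were higher, Prf1 (1.99), Nkg7 (1.72) and Gzma (2.07), and 5 when adjusted over the list alone (median 1.12, adjusted p = 1.45e-06, and adjusted p = 0.0517 with an estimated correlation). Ccl5 was higher as well (2.24), 1 of 4 cytokines with Tslp (0.91) and, chosen after their values were seen, Il23a (1.33) and Il15 (1.19). Of genes called one by one, Cldn7 (1.89) and Dsc2 (4.33 ± 0.50) were higher in KDM1B KO, and Cldn9 (-4.65 ± 0.46), Tjp3 (-3.34) and Crb3 (-4.87) were higher in KDM1A KO. H19 differed by -3.50 ± 0.60.

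In this direct comparison 409 genes were called, 165 higher and 244 lower in KDM1B KO than in KDM1A KO tumours. KDM1B KO replicates 1 and 2 had lower total counts and a lower Rn18s share than every KDM1A KO library, so genotype was partly confounded here too. T cell genes had a median of 1.11 (8 higher adjusted over the list alone, adjusted p = 1.05e-06, and adjusted p = 0.273 with an estimated correlation). Cytokines (0.37; adjusted p = 2.37e-04, and adjusted p = 0.249 with an estimated correlation), muscle (2.33; adjusted p = 2.5e-04, and adjusted p = 0.711 with an estimated correlation), immediate early (0.24; adjusted p = 0.00256, adjusted p = 0.399 with an estimated correlation and 0.0598 without KDM1B KO replicate 2) and checkpoint genes (0.50; adjusted p = 0.0167, adjusted p = 0.658 with an estimated correlation and 0.0719 without KDM1A KO replicate 3) passed camera, and the other 23 lists did not. Among these, the median, mean or test differed in sign for the partner, protease, cholesterol, stress response, endothelial, erythroid and mammary epithelial genes. The count was 128 and 173 without KDM1B KO replicates 2 and 1, 134, 177 and 136 without KDM1A KO replicates 1, 2 and 3, 246 without WT replicate 1, 657 without WT replicate 3, and 1286 with DESeq2. The interferon-stimulated genes called numbered 5 without KDM1A KO replicate 1 and 8 without KDM1A KO replicate 2 or KDM1B KO replicate 1 or 2. Cytotoxic genes numbered 0 by edgeR without KDM1A KO replicate 2 or 3 or KDM1B KO replicate 2 and 1 without KDM1A KO replicate 1, KDM1B KO replicate 1 or WT replicate 1. With all libraries 6 were at an unadjusted p under 0.05, and DESeq2 called 5 and limma 3. Cytokines numbered 1 without KDM1A KO replicate 1 or KDM1B KO replicate 1 or 2, and 2 without KDM1A KO replicate 2 or 3, KDM1B KO replicate 3 or WT replicate 1 or 2.

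Across 15462 genes the effects of the 2 knockouts on 4T1 tumours correlated at a Pearson r of 0.518, from 0.34 to 0.647 with a library left out, and a Spearman rho of 0.457. Genes are not independent replicates, and both comparisons shared the 3 WT libraries. In 20 simulations of unchanged groups against those controls r averaged 0.518 ± 0.0168 and rho 0.466, and 66.9% of genes had the same sign against 67% observed. These 3 measures were close to those of groups without any effect. The simulation held no effects, so they cannot tell whether effects that are present were alike. The covariance was 0.313 observed against 0.132 simulated, a difference of 0.181. The simulation left out any pairing of KDM1A KO and WT tumours by number. Both knockouts raised 18 genes, among them Cldn3, Socs1, Akr1c13 and Xlr, where independent lists would share 1.17. Both lowered 15 genes, among them Bmp7, Mgp, Ace and Ier3, where independent lists would share 0.57, values that ignore the shared WT libraries. Unchanged groups simulated against those libraries shared 0 calls in either direction, which does not measure sharing among genes that did change. Rdh10 rose in KDM1B KO and fell in KDM1A KO, and Gipc2 and Dennd3 did the reverse, Rdh10 and Dennd3 being chosen after their values were seen. With 3 WT tumours the controls could not be split, so part of the excess in covariance and shared calls may come from the shared controls.

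The comparison of KDM1B KO with WT MDA-MB-231 tumours asked the same question in a human line grown in mice without T cells. Of 34 tested interferon-stimulated genes 14 fell and none rose. IFIT3 went from 102 ± 4.82 CPM in WT to 32.4 ± 2.93 CPM in KO (SD, n = 3 each), a log2 fold change of -1.66 ± 0.12 (edgeR adjusted p = 0.000296), and OASL, an antiviral oligoadenylate synthetase-like protein, from 80.2 ± 20.5 to 10.2 ± 1.29 CPM (-2.97 ± 0.21, adjusted p = 0.000296). NDRG1, a gene induced by hypoxia, fell from 1978 ± 736 to 529 ± 104 CPM (-1.90 ± 0.28, adjusted p = 0.00522). ASNS, the asparagine synthetase, rose from 43.8 ± 10.2 to 159 ± 19.6 CPM (1.86 ± 0.18, adjusted p = 0.000992). SPP1, the secreted matrix protein osteopontin, fell from 64.1 ± 29.1 to 2.90 ± 1.31 CPM (-4.47 ± 0.42, adjusted p = 0.000957).

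Of 14452 genes tested in the MDA-MB-231 tumours 949 were called, 313 higher and 636 lower in KO, and 499 of them changed at least 2-fold, 97 higher and 402 lower. The largest rises were in SESN3, a stress-induced sestrin (2.61 ± 0.23), KLF15, a transcription factor (2.02), CHAC1, a glutathione-degrading enzyme (1.84), SLITRK6, a membrane protein of neurons (1.77), SERPINB7 (1.74), CTH, which makes cysteine (1.72), CXorf57 (1.61), CTGF, a matrix-associated growth factor (1.53), and LINC00665 (1.53). EMC10, a subunit of the complex that inserts membrane proteins, fell from 17.9 ± 2.23 to 0.272 ± 0.0113 CPM (-6.03 ± 0.22, adjusted p = 5.19e-06). In culture EMC10 was far below WT in KO replicate 2 but above WT in KO replicate 1, so both KO cultures did not share this fall. Falls followed in the mucins MUC5B (-4.91 ± 0.90) and MUC5AC (-4.36), TFF3, a mucosal trefoil peptide (-4.81), CDH13, a cadherin (-4.79 ± 0.29), TNS1, a focal adhesion protein (-4.54), ITGB4, an integrin of hemidesmosomes (-3.94), IGFBP3, which binds insulin-like growth factors (-3.69), and JUP, plakoglobin of cell junctions (-3.67). MUC5B and MUC5AC are repetitive neighbours whose reads are uncertain. In the KO tumours 18997 ± 278 genes had at least 1 count against 17178 ± 284 in WT, and 27.7% of tested genes were separated against the 10% of chance. By chromosome region the KO tumours followed KO culture replicate 2 (r 0.917) and not replicate 1 (r -0.117). Differences between KO cells other than KDM1B loss may therefore add to these calls, which was not tested.

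In the KO tumours 33 of 34 interferon-stimulated genes had negative fold changes, with a median of -0.78, and 23 fell when adjusted over the list alone (adjusted p = 3.63e-25, and adjusted p = 0.00875 with an estimated correlation). IFIT1 (-1.61) and IFIT2 (-1.70) fell beside IFIT3. Of 16 sensing and silencing genes 3 fell, the double-stranded RNA receptor TLR3 (-1.86) and the helicases DHX58 (-2.92) and DDX58 (-0.78). When adjusted over the list alone 4 fell and 1 rose (median -0.135, adjusted p = 0.0353, adjusted p = 0.17 with an estimated correlation, and 0.106 and 0.193 without KO replicate 1 and WT replicate 2). Of 27 cytokines 4 fell, the granulocyte factor CSF3 (-1.46), the chemokines CCL28 (-1.35) and CXCL16 (-2.24) and the inflammatory cytokine IL1B (-2.70), and 7 when adjusted over the list alone (median -0.80, adjusted p = 2.16e-05, and adjusted p = 0.119 with an estimated correlation). STAT6 (-0.69), JAK3 (-2.65) and STAT5A (-0.79) fell among 34 receptor and JAK-STAT genes (7 adjusted over the list alone; adjusted p = 0.00964, adjusted p = 0.119 with an estimated correlation and 0.0536 without WT replicate 2). Of 25 NF-kB genes 5 fell, among them TNFAIP2 (-0.93), the adhesion molecule ICAM1 (-2.04), the prostaglandin synthase PTGS2 (-1.70), MAP3K14 (-0.78) and IKBKE, chosen after its value was seen (-0.69). When adjusted over the list alone 9 fell and 1 rose (median -0.42, adjusted p = 1.17e-04, adjusted p = 0.482 with an estimated correlation and 0.163 without WT replicate 2). For antigen presentation, HLA-B (-1.26) and B2M (-0.51) fell of 11 class I genes (adjusted p = 0.00964, adjusted p = 0.17 with an estimated correlation and 0.12 without WT replicate 2). So did CD74, the invariant chain (-4.19), and CTSS, the protease that trims it (-2.05), of 3 class II genes (adjusted p = 1.86e-04, and adjusted p = 0.0954 with an estimated correlation). Reads of HLA-B are uncertain among its paralogs. CD274, the ligand PD-L1, rose (0.76) and LGALS9, a galectin, fell (-2.51) among 8 checkpoint genes (adjusted p = 0.616). JAK3, LGALS9, CD74 and DHX58 had low levels, so their fold changes rest on few counts. Their mean log2 CPM over the MDA-MB-231 tumours and cultures together was -1.885, -2.5, -0.79 and -0.65.

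Of 24 hypoxia and glycolysis genes 9 fell and none rose in the KO tumours, and 12 fell when adjusted over the list alone (median -0.54, adjusted p = 4.39e-11, and adjusted p = 0.278 with an estimated correlation). Beside NDRG1, the glucose transporter SLC2A3 (-1.34), the peptide hormone ADM (-2.27) and the prolyl hydroxylase EGLN3 (-1.95) led them. Of 20 stress response genes 7 rose and 1 fell, and 9 rose and 1 fell when adjusted over the list alone (median 0.21, adjusted p = 1.94e-05, and adjusted p = 0.0604 with an estimated correlation). ASNS, CHAC1, PHGDH of serine synthesis (1.15) and TRIB3, a pseudokinase (0.86), led the rises. Of 22 epithelial-mesenchymal transition genes 6 fell, and 7 when adjusted over the list alone, among them the integrin ITGA5 (-1.57), the keratin KRT19 (-5.49), the collagen crosslinker LOX (-1.76) and the claudin CLDN4 (-1.62). Its members that fell belong to epithelial and mesenchymal states alike (median -0.40, adjusted p = 1.45e-05, and adjusted p = 0.17 with an estimated correlation). CCNB2 (-0.69) and AURKA (-0.57), of mitosis, and the cell cycle inhibitor CDKN1A (-1.63) fell among 26 cell cycle genes (7 adjusted over the list alone; median -0.195, adjusted p = 0.0353, adjusted p = 0.681 with an estimated correlation, and 0.379 and 0.302 without KO replicate 3 and WT replicate 2). Single members were called in lists that did not pass, with ADAMTS1, a matrix protease, up (1.27) and PLAUR (-0.80) and MMP14 (-0.71), of matrix breakdown, down. So were the imprinted gene PEG10, up (0.68), and DUSP1, an early phosphatase, down (-1.44). The cholesterol list had a median of 0.128 and a mean of -0.0426 and did not pass.

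Of 9 endothelial markers 4 fell in the KO tumours, PECAM1 (-1.89 ± 0.15, from 21.6 ± 2.15 to 5.82 ± 0.470 CPM), ESAM (-1.66), the cadherin CDH5 (-1.98) and EGFL7 (-0.88), and 5 when adjusted over the list alone. Their median was -0.76 (adjusted p = 3.3e-08, and adjusted p = 0.0435 with an estimated correlation). Of 9 mammary epithelial genes 4 fell, KRT19, the adhesion receptor CD44 (-1.11), KRT18 (-0.52) and CD24 (-2.72), and 5 when adjusted over the list alone (median -1.11, adjusted p = 1.94e-05, and adjusted p = 0.136 with an estimated correlation). The lysosomal CD68 (-0.95) and the receptor CSF1R (-1.67) fell of 6 macrophage genes (adjusted p = 0.0353, and adjusted p = 0.214 with an estimated correlation), a call lost without KO replicate 1 (adjusted p = 0.147). Single changes were COL6A3, a collagen, up (0.74), and KRT15 (-2.67), the granzyme GZMA (-3.73, from 2.16 to 0.162 CPM) and ZBTB46 (-1.08) down. The table counted human genes, while the vessels and immune cells of the host were mouse, and T, B, cytotoxic, neutrophil, dendritic and erythroid lists had too few tested members for camera.

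The count of called genes in MDA-MB-231 tumours was 2951 without WT replicate 2, which differed at least 2-fold from WT replicates 1 and 3 at 516 and 357 genes, where those 2 differed at 14. It was 289, 330 and 365 without KO replicates 3, 2 and 1, 372 without WT replicate 3, and 1618 with DESeq2. Hypoxia genes called down numbered 21 without WT replicate 2, 4 without WT replicate 3 or KO replicate 1 or 2, and 5 without KO replicate 3, and stress response genes numbered 4 or 5 without KO replicate 3 or 1 or WT replicate 3. Cytokines called down numbered 10 without WT replicate 2.

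The comparison of KDM1B KO with WT cultures asked what differed with KDM1B loss in the human cells grown in culture. No gene passed in edgeR with 2 libraries per genotype, while 1129 of 15039 genes were at an unadjusted p under 0.05, DESeq2 called 156 (31 higher, 125 lower) and limma called 4. The rising genes of smallest p, none of them called, were ASNS at 81.9 ± 3.43 against 36.6 ± 0.207 CPM (SD, n = 2 each; 1.16 ± 0.09, edgeR adjusted p = 0.206), RHBDF1, a rhomboid-like protein (0.87, adjusted p = 0.369), and DDIT4, a stress-induced inhibitor of mTOR (1.30, adjusted p = 0.475). Those of smallest p with lower values were the chemokine CXCL1 at 0.307 ± 0.0623 against 9.19 ± 0.606 CPM (-4.89 ± 0.26, adjusted p = 0.14), TMEM150B (-4.15 ± 0.23, adjusted p = 0.14) and RFPL4A. RFPL4A had 0 counts in both KO cultures and 4.61 ± 0.114 CPM in WT, at least 128.7 times lower in KO against a floor of 3 counts per library (adjusted p = 0.206).

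In culture 7 of 24 lists passed camera, 0 with an estimated correlation and 3 with fry. Of 26 cytokines 7 were lower when adjusted over the list alone (median -0.61, adjusted p = 1.71e-11, and adjusted p = 0.341 with an estimated correlation), and of 26 NF-kB genes 5 (median -0.23, adjusted p = 3.47e-07, and adjusted p = 0.476 with an estimated correlation). Of 20 stress response genes 3 were higher when adjusted over the list alone (median 0.16, adjusted p = 8.46e-07, and adjusted p = 0.341 with an estimated correlation). The 28 interferon-stimulated genes had a median of -0.21 with 1 lower when adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.511 with an estimated correlation), a call lost without KO replicate 1 (adjusted p = 0.185). Receptor (adjusted p = 0.0203, and adjusted p = 0.513 with an estimated correlation), cell cycle (adjusted p = 0.0299, and adjusted p = 0.476 with an estimated correlation) and mammary epithelial genes (adjusted p = 0.0106, and adjusted p = 0.476 with an estimated correlation) passed downwards, and the other 17 lists tested did not. The cell cycle call ended without KO replicate 1 or 2 or WT replicate 1 or 2 (0.185, 0.0735, 0.0783 and 0.0761). The receptor call ended without KO replicate 2 or WT replicate 1 or 2 (0.894, 0.0728 and 0.113), and the mammary epithelial call without KO replicate 2 (0.285). The lists whose median, mean or test differed in sign were the partner, checkpoint, immediate early, T cell, cholesterol and keratinocyte genes, all of which did not pass. The KO cultures differed from each other at least 2-fold at 304 genes and the WT cultures at 0, and 4964 or 6797 genes were called without KO replicate 1 or 2, each lone KO library being assumed to vary like WT. EMC10 had 2310 counts in KO replicate 1 and 7 in replicate 2, against 838 and 807 in the WT cultures.

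**Figure D3:**
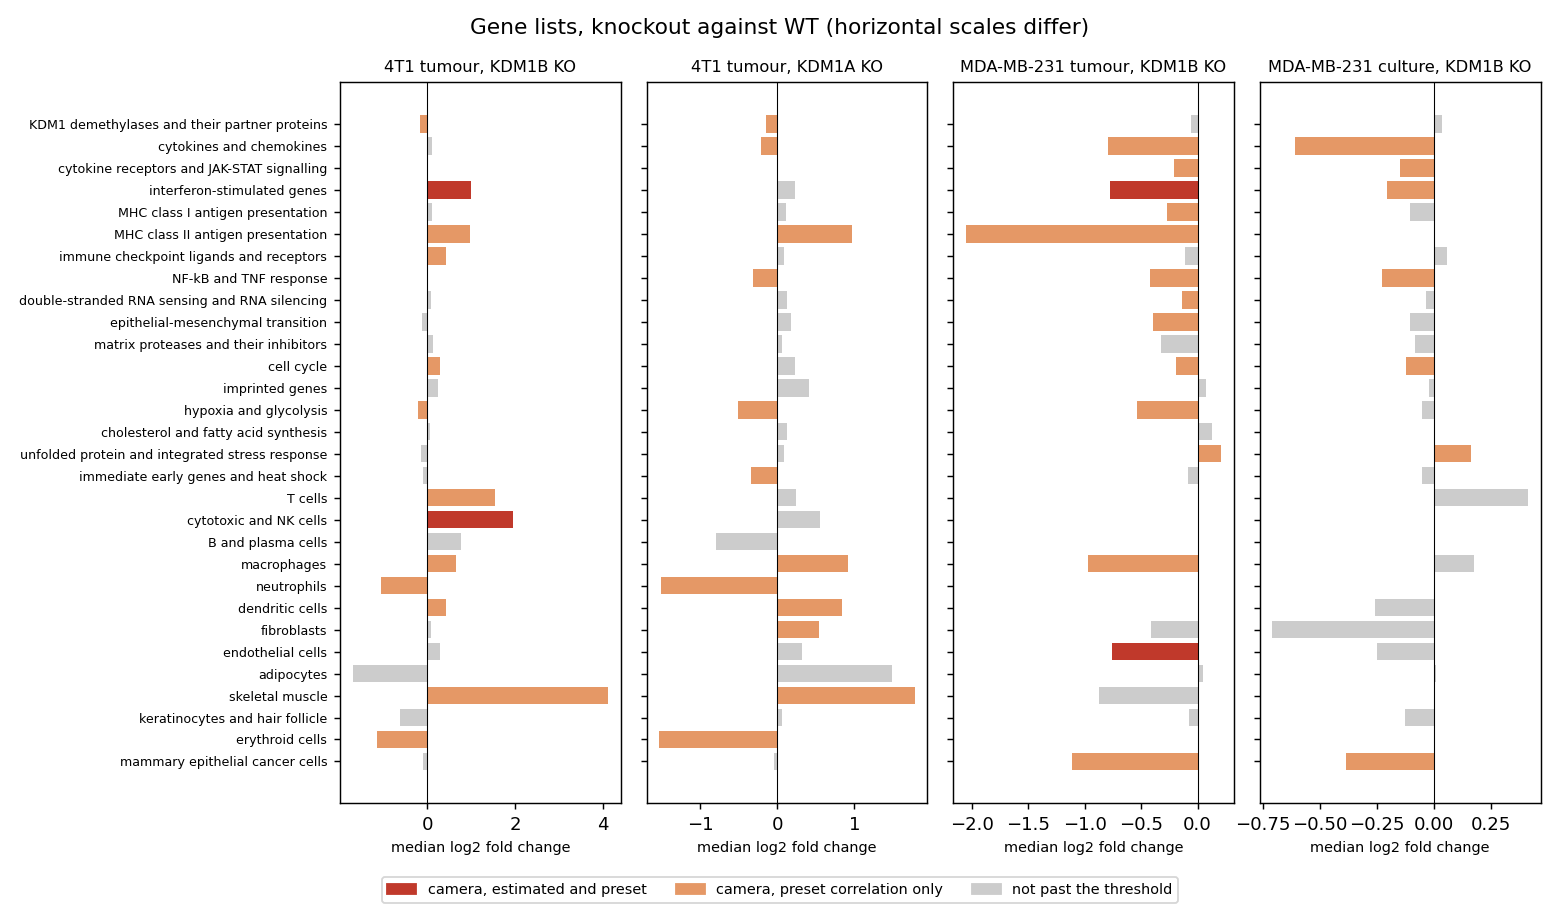
Median log2 fold change of each gene list, KO against WT, in 4 panels with different horizontal scales, for lists of at least 3 tested members. Red bars passed camera with a preset and with an estimated correlation, orange bars only with the preset one and grey bars with neither, and red marks 2 lists in 4T1 KDM1B KO tumours, 0 in KDM1A KO tumours, 2 in MDA-MB-231 tumours and 0 in culture.

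The effect of KDM1B KO on MDA-MB-231 cells was tested for a difference between tumour and culture in 1 fit, where 28 of 15603 genes were called. The culture effect averaged KO replicates 1 and 2, of which replicate 1 did not follow the tumours by chromosome region (r -0.117). The KO effect was higher in tumours for 8 genes and lower for 20, with 1321 genes at an unadjusted p under 0.05. The effect on IFIT3 was lower in tumours by -1.68 ± 0.19 (edgeR adjusted p = 0.00954), with -1.66 in tumours and -0.01 in culture, and IFIT1 (-1.52 ± 0.19) and IFIT2 (-1.97 ± 0.24) differed alike. SPP1 (-3.93), TNS1 (-5.02) and DDIT4 (-2.91) also had lower effects in tumours, and ADAMTS1 had a higher one (1.57). Of 26 lists the interferon-stimulated genes (4 of 35 lower, median -0.675, adjusted p = 1.93e-10, and adjusted p = 0.0273 with an estimated correlation), the hypoxia genes (median -0.43, adjusted p = 1.93e-10, and adjusted p = 0.56 with an estimated correlation) and the epithelial-mesenchymal transition genes (median -0.33, adjusted p = 0.0105, and adjusted p = 0.56 with an estimated correlation) differed. The number of genes called was 0 in edgeR without either WT culture, 492 without KO culture replicate 2, 20 without KO culture replicate 1, and 199 without WT tumour replicate 2. It was 11, 5 and 2 without KO tumour replicates 1, 2 and 3, and 10 without WT tumour replicate 3. DESeq2 called 194 and limma 40.

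Across lines, the effects of KDM1B KO on 4T1 and MDA-MB-231 tumours did not follow each other over 10992 genes (Pearson r -0.014, Spearman rho -0.0185), nor did those on 4T1 tumours and MDA-MB-231 cultures (r -0.0223). The effects on MDA-MB-231 tumours and cultures correlated at r 0.363 and rho 0.258 over 13987 genes, with r from 0.12 to 0.52 when a library was left out. Over the 10110 genes with enough counts and a position, the tumour effect correlated at r 0.523 with KO culture replicate 2 and at 0.0208 with replicate 1. Genes that rose in 4T1 and fell in MDA-MB-231 KO tumours numbered 12, where independent lists would share 1.79. They include IFIT1, IFIT2, IFIT3, IFI44, OAS2, OAS3, CLDN7, DSC2 and GZMA. Genes lower in both numbered 4, CELSR1 and, chosen after their values were seen, EPN2, KDELR3 and TRIOBP, where independent lists would share 1.52. No gene rose in both by edgeR calls (0.823 expected), and ADAMTSL3, chosen after its values were seen, fell in 4T1 and rose in MDA-MB-231 tumours. The mean effect on interferon-stimulated genes was 1.12 in 4T1 and -0.97 in MDA-MB-231 tumours, a difference of 2.09 (exact permutation p = 0.005, the smallest that 400 relabellings can give, adjusted p = 0.0283 over 17 lists).

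By chromosome region, the KO effect in MDA-MB-231 tumours followed that of KO culture replicate 2. Over 153 windows of 20 Mb the medians correlated at r 0.917 and rho 0.76 with replicate 2 and at r -0.117 with replicate 1, across 10110 genes. With regional medians taken off, an alternative added after the data were seen, 459 of the 499 genes called at 2-fold remained. The adjusted p-values were kept from the main fit, so only genes that their regional median had carried past 2-fold could drop out. This recount cannot tell whether other differences between KO cells added to the calls.

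**Figure D4:**
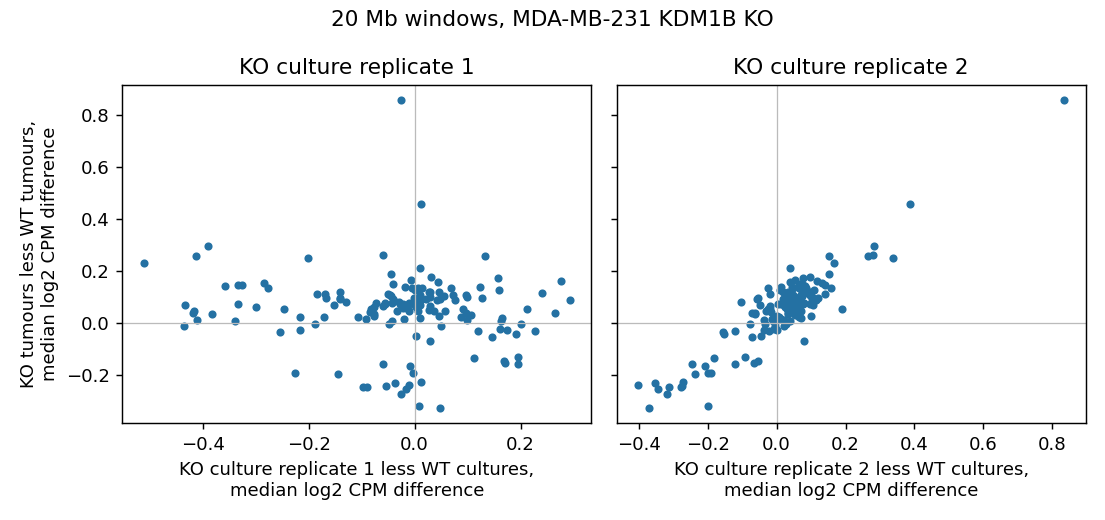
Median log2 CPM difference between KO and WT in 20 Mb windows with at least 15 genes, in MDA-MB-231 tumours (vertical axis) against KO culture replicate 1 (left) and replicate 2 (right), 1 point per window. The points spread without a trend on the left (r -0.117) and along a line on the right (r 0.917).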

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

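The comparisons with scaling, T cell markers and the culture medians were chosen after the interferon result had been seen. Interferon-stimulated genes, which cells switch on to resist viruses, differed between the tumour models under KDM1B loss. The mean effect was 2.09 log2 units higher in 4T1 than in MDA-MB-231 tumours, a difference flagged by permuting the genotype labels. Scaling of the libraries did not explain this, because the list stood at -0.785 in MDA-MB-231 and 0.997 in 4T1 tumours after the median of all genes was taken off. More T and NK cells in 4T1 KO tumours could have raised these genes, and T cell markers had a median of 1.55, while the MDA-MB-231 tumours grew in mice without T cells. With a T cell score in the fit the interferon median was 0.796 with 0 genes called by edgeR, but score and genotype were confounded, so this could not tell. A loss in MDA-MB-231 KO cells in any setting might add to the difference, but the list medians of -0.324 and -0.162 in the KO cultures against -0.707 in tumours, over 28 genes, could not tell either.

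Permuting the labels flagged 4 further lists whose KDM1B KO effects were higher in 4T1 than in MDA-MB-231 tumours. The differences were 0.482 for cytokine receptors and JAK-STAT genes, which carry cytokine signals, 0.527 for RNA sensing and silencing genes, 0.744 for checkpoint genes, which restrain lymphocytes, and 3.36 for class II antigen presentation genes. The members tested differed between the lines, with 8 class II genes in 4T1 and 3 in MDA-MB-231 and 19 and 8 checkpoint genes, and the 4T1 table counted genes of host immune cells, which the human table did not. The 12 genes up in 4T1 and down in MDA-MB-231 tumours and the 1 with the reverse, ADAMTSL3, were flagged because their calls had opposite directions, and their differences were not tested.

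The interaction test flagged 28 genes whose KDM1B KO effect differed between MDA-MB-231 tumours and cultures. The effect in tumours less that in culture was -1.68 for IFIT3, -1.97 for IFIT2 and -1.52 for IFIT1, which bind viral RNA. It was -3.93 for SPP1, osteopontin, -5.02 for TNS1, of focal adhesions, -2.91 for DDIT4, which restrains mTOR, and 1.57 for the protease ADAMTS1. RFPL4A, a ubiquitin ligase relative, had a difference of 6.07, a fitted value that depends on the prior count because the KO cultures held 0 counts. The list medians flagged by the same test were -0.675 for interferon-stimulated genes, -0.431 for hypoxia genes and -0.328 for epithelial-mesenchymal transition genes. With an estimated correlation the interferon list passed (adjusted p = 0.0273) and the other lists did not (adjusted p = 0.56 each). Different KO cells could add to these differences, since the tumours followed KO culture replicate 2 by region (window r 0.917) and not replicate 1 (-0.117). The interferon median, however, was -0.162 in replicate 2 against -0.707 in tumours, so for this list the difference did not rest on replicate 1 alone. For the hypoxia and epithelial-mesenchymal transition lists no value of replicate 2 alone is given here. With 1 KO culture left, which genes would stay called could not be judged.

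With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave the most calls in each comparison, so 1 of 10 splits reached its count. It gave 121 against at most 30 in another split for KDM1B KO against WT in 4T1, 432 against at most 0 for KDM1A KO, 409 against at most 0 for the direct comparison and 949 against at most 0 in MDA-MB-231 tumours. For KDM1A KO against WT the numbers were treated as pairing the tumours. Of the 4 splits parting all 3 pairs, those other than the real one gave at most 0 calls.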

How the results depend on the processing

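No named gene that was called in the main fit or in an alternative turned its direction between them. Turns of genes called in neither were not counted. The calls of the interferon-stimulated gene list in the 4T1 and MDA-MB-231 KDM1B KO tumours kept their direction with an estimated correlation. With single libraries left out, called genes ranged from 15 to 108 for KDM1B KO against WT in 4T1 tumours, 4 to 1516 for KDM1A KO, 128 to 657 between the knockouts, 289 to 2951 in MDA-MB-231 tumours, 0 to 6797 in culture and 0 to 492 for the tumour-culture difference. The correlations of effects ranged from -0.038 to 0.0109 (4T1 and MDA-MB-231 tumours), -0.0433 to 0.0171 (4T1 tumours and cultures), 0.12 to 0.52 (MDA-MB-231 tumours and cultures) and 0.34 to 0.647 (both 4T1 knockouts). DESeq2 called 831 genes for 121 by edgeR, 1688 for 432, 1286 for 409, 1618 for 949, 156 for 0 and 194 for 28 in that order, and the cause was not tested. At 2-fold 269 genes remained for KDM1A KO and 499 in MDA-MB-231 tumours, by construction. Without the filter on low counts, edgeR called 3 genes in culture for 0 and 98 for 28 in the tumour-culture difference, and limma called 4 in culture (the cause was not tested). With an estimated correlation the lists called went from 13 to 2 (4T1 KDM1B KO), 12 to 0 (KDM1A KO), 7 to 0 (between knockouts), 14 to 2 (MDA-MB-231 tumours) and 7 to 0 (culture), and with fry to 3, 0, 3, 14 and 3, as these tests allow for correlated genes or ask another question. Over genes called in at least 1 of them, the correlation of 4T1 tumours with cultures was -0.0971 for -0.0223 over all, and the cause was not tested. The cultures had the highest total counts and 0 calls by edgeR, and the lowest depth, 22923212 counts, was in a 4T1 WT tumour.

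With the replicate number as a block 463 genes were called for KDM1A KO against WT, where the numbers were treated as pairing the samples. There the calls of Bmp7, S100a8, S100a9, Ly6g, Hmg20b, Nfkbia, Aif1 and C1qa were lost, and no other gene named by the fixed rule and no list changed its call, 12 being called as before. Members called went from 4 to 2 neutrophil, 3 to 1 macrophage, 3 to 2 NF-kB, 5 to 6 cytokine, 1 to 2 immediate early and, in both directions together, 2 to 4 epithelial-mesenchymal transition and 3 to 4 stress response genes, from 0 to 1 in the hypoxia, cell cycle, fibroblast and mammary epithelial lists, and from 1 up and 1 down to 2 down among partner genes. Elsewhere the samples shared only a number, and the block gave 116 genes for KDM1B KO against WT in 4T1, 513 between the knockouts, 403 (96 higher, 307 lower) for 949 in MDA-MB-231 tumours, 0 in culture and 0 for 28 in the tumour-culture difference. The lists called under the block were 12, 7, 14 and 9 for the first 4 of these. The same-numbered correlations were 0.179, -0.142 and 0.393 for 4T1 KDM1B KO and WT, -0.011, -0.351 and 0.144 between the knockouts, -0.594, -0.294 and 0.31 in MDA-MB-231 tumours and 0.034 in culture. In none of these comparisons of 3 pairs did every sample correlate best with its own number.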

Other observations

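The tests on gene families, copy number, sample labels, olfactory receptors and silent genes were chosen after the values had been seen. Histone genes, which supply the proteins that package DNA, were lower in MDA-MB-231 KDM1B KO tumours. Of 37 tested histone genes 9 fell and 33 had negative fold changes, with a median of -0.954 (camera adjusted p = 0.0391 with an estimated correlation over 22 gene families). Among those chosen after their values were seen, the linker histone HIST1H1C went from 66.6 ± 8.02 to 29.5 ± 1.65 CPM (SD, n = 3 each; -1.17 ± 0.13, edgeR adjusted p = 0.00159), and the core histones HIST1H2BD (-1.01) and HIST2H2BE (-1.18) fell too. In culture the histone median was -0.147 (camera adjusted p = 0.587 with an estimated correlation). In 4T1 KDM1B KO tumours the 91 genes with the same symbol prefixes had a median of 0.423 (camera adjusted p = 0.1 with an estimated correlation). In mouse those prefixes also match the H2 antigen presentation genes, so this is not a median of histones alone and gives no histone direction in 4T1.

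Keratins, the filament proteins of epithelial cells, were lower in the same tumours, with 6 of 12 called down and a median of -1.79. The family did not pass with an estimated correlation (camera adjusted p = 0.139). KRT81, chosen after its values were seen, went from 142 ± 79.0 to 27.1 ± 6.31 CPM (-2.39 ± 0.42), beside KRT19 and KRT18.

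The KO cultures differed from each other, and the MDA-MB-231 KO tumours followed replicate 2 by region. KO cells with different chromosome copy numbers could explain this, and the 20 Mb window medians correlated at r 0.917, where 1000 shuffles of gene positions gave at most 0.572. Genes on chromosome 13 had medians of 0.256 in tumours and 0.259 in replicate 2, but its windows differed in sign. From 20 to 80 Mb their medians were 0.26 to 0.855 in tumours and 0.28 to 0.834 in replicate 2. From 80 to 120 Mb they were -0.275 and -0.239 in tumours and -0.318 and -0.401 in replicate 2. Genes on chromosome 3 had a median of -0.292 in replicate 1 alone. GC content or gene length did not explain it, as r was 0.916 with their trends taken off. A WT culture like those sequenced, labelled as KO replicate 1, did not explain it either. KO replicate 1 lay at least 2-fold from the WT mean at 158 genes, where the WT cultures differed from each other at 0. The count cannot exclude a WT culture that had drifted from them. The labels name no clones, and whether KDM1B loss itself acted on these regions was not tested.

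More genes with few counts appeared in the MDA-MB-231 KO tumours. Depth did not explain this, since at an equal 37551440 counts the lowest KO library had 18663 genes detected and the highest WT library 17317. RNA of the mouse host was a poor explanation, as olfactory receptor genes, expressed mainly in the nose, were detected at 110 to 116 of 375 in KO and 10 to 14 in WT tumours. It was not excluded, since 9 olfactory receptor genes passed the filter in the 4T1 tumours. Traces of genomic DNA could explain it, but the test could not tell. It used 3093 genes silent in culture that had counts in at least 1 tumour library. Their counts followed gene length at a Spearman coefficient of 0.252 to 0.266 in KO and 0.0297 to 0.0628 in WT libraries. KO libraries detected 1450 to 1634 of these genes and WT libraries 382 to 486. The genes thus entered mostly through the KO libraries, and many WT values were tied at 0, so the coefficients were not compared on equal terms. These genes held 0.0177% to 0.0182% of counts in KO and 0.013% to 0.0143% in WT.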
